A study of Mus musculus with 2 samples.

How the data were processed

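Single sorted cells from mouse small intestinal organoids were profiled by SORT-seq, a plate method in which each cell is sorted into 1 well of a 384-well plate and its polyadenylated RNA is copied with a primer that carries a well barcode and a molecular barcode, pooled and amplified by in vitro transcription (CEL-Seq2). Per the labels, there was 1 plate of Ngn3-RFP-positive cells from organoids given DMSO for 48 h and 1 plate from organoids given ISX-9 for 48 h. The authors deposited 1 table of raw counts per plate, with genes in rows and the 384 wells in columns, as the number of reads per gene and well. These counts are reads and not molecules: the molecular barcode has 4 bases, which give 256 combinations, and the largest deposited values are 61032 in the DMSO plate and 30676 in the ISX-9 plate. Amplified copies of 1 molecule are therefore counted more than once, and the Poisson intervals cover counting error only.

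The submitters' processing notes name BWA without a version and a human genome build. The gene rows of the deposited tables carry mouse symbols with a chromosome. Of 16943 nuclear genes, 93.7% had a symbol that is in the GENCODE mouse annotation release M21, and 99.9% of those stood on the chromosome given there. The build behind the gene models is thus open, and chromosomes are given without coordinates. The counting rule for reads shared between paralogs is not given in the sources used here, so values of the Reg3, defensin, Clca, Mptx and Lyz families are uncertain between members. A gene listed for 1 plate was set to 0 in the other when it was not listed there, which applied to 1107 rows listed for the DMSO plate alone and 1395 listed for the ISX-9 plate alone. Each listed row had at least 1 read.

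Reads of ERCC spike-ins and mitochondrial genes were taken out of the totals. Wells with at least 2000 reads to nuclear genes and at least 500 nuclear genes with a read were kept, which left 300 of 384 DMSO wells and 290 of 384 ISX-9 wells. Doublets were not called; leaving out the top 5% of wells by reads was an alternative. Rn45s, a ribosomal RNA precursor, stayed in the totals as fixed beforehand and took 13.0% of nuclear reads in the DMSO plate and 6.25% in the ISX-9 plate.

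Each treatment has 1 library. Cells of a plate are not replicates of a treatment, so no test between treatments was made and no p-value is given. For each gene, reads were summed over the kept wells of a plate and expressed as CPM, counts scaled to the same total of nuclear reads for both plates, with an exact 95% Poisson interval. The share of wells with a read has an exact 95% Clopper-Pearson interval. The difference is the log2 ratio of (CPM + 5), ISX-9 over DMSO, which understates the difference of genes with low values. Where a count was 0, 3 counts were taken as the floor. To compare shares of wells at the same depth, each well was also thinned to 2000 reads, which left out no kept well.

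The genes, lists, markers and alternatives were fixed before the data were examined, except where stated. The text names the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with a read in at least 10% of kept wells of at least 1 plate, at least 100 reads over both plates and a share of wells that differs in the same direction, without ribosomal protein genes, mitochondrial genes, spike-ins and predicted genes. It adds Neurog3, up to 4 members with the largest absolute log2 ratio of each list among those with a mean of at least 10 CPM, and markers named for the class they mark. There were 25 lists, 10 of them cell type markers and 15 of them pathways, with 268 genes. Genes were matched by symbol alone. Of these, 9 genes (Aldh3a1, Clca3a1, Defa22, Defa30, Fosl1, Gsta1, Lct, Sh2d6 and Sst) had no row under that symbol and were not analysed here. For a list, the median log2 ratio of the measured members is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these 2 libraries.

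Wells of both plates were clustered together: reads were scaled to 10000 per well and log-transformed, the 2000 most variable genes without ribosomal protein genes were standardised, and 15 principal components, a graph of 15 neighbours weighted by shared neighbours and the Leiden algorithm at resolution 1 were used. A cluster was named after a class when at least 3 of its fixed markers had a read in at least 25% of its wells and were at least 2-fold above all other wells (ratio of CPM + 10), when at least 1 of them was among the top 10 genes by fold and no other class had more there, and when neither Rn45s nor Lars2 was among the top 10. Only the markers were fixed beforehand. The requirement of a marker among the top 10 genes and the exclusion by Rn45s and Lars2 were added after the clusters were seen, and they left clusters 2, 4 and 8 and cluster 1 unnamed, respectively. Levels within a class were computed in the same way from its wells. Intervals over resampled wells are the central 95% of 1000 draws of the wells with replacement, a test added after the values were seen. The unfolded protein response list was also compared within classes after its median over all wells was seen. Alternatives were median-of-ratios size factors, ERCC spike-in scaling, means over wells, stricter (6000 reads and 1000 genes) and looser (500 reads and 200 genes) well filters, thinned wells, leaving out the top 5% of wells, a pseudocount of 1 CPM, shares of wells, all list members with a read, other clustering resolutions (0.6 and 1.5), 30 principal components, clustering without cycling markers and centring of genes within plates. Leaving out Rn45s, the wells of clusters 1 and 2, or each gene's highest well, clustering without the named genes or without all listed genes, and naming clusters by the count of markers alone, were chosen after seeing the data.

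The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. They were tested on simulated data: overdispersed counts were drawn for the real genes from the real means and library sizes, with 200 of the 9106 genes at 10 CPM or more changed in the ISX-9 wells. All 50 genes changed 2-fold upward and all 50 changed 2-fold downward had the right sign relative to the unchanged genes, with median log2 ratios of 0.94 and -0.75, and the genes changed 4-fold gave 1.85 and -1.56, since the pseudocount draws ratios toward 0. Of 40 lists of 10 unchanged genes, 1 fell outside the central 95% of random lists. These simulated wells had no cell classes and their genes varied independently. Members of a real list can vary together, which this check does not cover. In 590 simulated wells from 4 gene programmes with strong markers, 7 clusters were found (adjusted Rand index 0.704), and 100% of wells were given the class they were drawn from, which is an easier case than the real wells.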

Results

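The data compare Ngn3-RFP-positive cells sorted from mouse jejunal and ileal organoids after 48 h with the small molecule ISX-9 (isoxazole 9, known as an inducer of neuronal differentiation) with those sorted after 48 h with the solvent DMSO. Neurog3 (Ngn3) encodes the transcription factor that starts the enteroendocrine lineage, and the red fluorescent reporter at this gene, homozygous in these animals, marks cells that express it or did so shortly before. The question named by the series is how ISX-9 acts on the fate of endocrine progenitors. There is 1 plate per treatment, so every difference below is one between 2 libraries and has no replicate check.

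The DMSO plate held 21398070 reads and the ISX-9 plate 17062599. Mitochondrial genes took 26% of the reads in the DMSO plate and 24.7% in the ISX-9 plate. The 300 kept DMSO wells had a median of 26340 nuclear reads and 2629.5 genes, and the 290 kept ISX-9 wells had 22509.5 reads and 2981 genes. A gene with no read in a plate was below 0.203 CPM in DMSO and below 0.254 CPM in ISX-9, taking 3 counts as the floor. Over the 9106 genes with a mean of at least 10 CPM, the median log2 ratio was 0.15, so a gene or list near that value did not stand apart from the rest. Median-of-ratios scaling shifts log2 ratios of abundant genes by -0.20 and ERCC scaling by -0.25. The Poisson intervals below cover counting error only, because reads copied by amplification are not independent molecules, and intervals of shares of wells cover the sampling of wells from 1 plate.

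Neurog3 (chromosome 10) was 4.38-fold higher in the ISX-9 plate, at 2990 CPM (95% Poisson interval 2959 to 3021) against 679 CPM (665 to 692), a log2 ratio of 2.13. A Neurog3 read was found in 72.8% of ISX-9 wells (67.2 to 77.8) and in 49% of DMSO wells (43.2 to 54.8). After thinning to 2000 reads per well these shares were 47.2% and 26.3%. All 11 measured markers of the enteroendocrine progenitor list had positive log2 ratios, 6 of them at least 2-fold, and the list median of 1.28 lay above all of the random lists (percentile 100, central 95% of random lists -0.10 to 0.39). Among them Pax4, a transcription factor of early endocrine cells, stood at 212.7 against 45.2 CPM (log2 ratio 2.12), the corepressor Rcor2 at 79.1 against 19.9 CPM (1.76) and the Notch-modifying glycosyltransferase Mfng at 18.6 against 1.76 CPM (1.81).

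**Figure D1:**
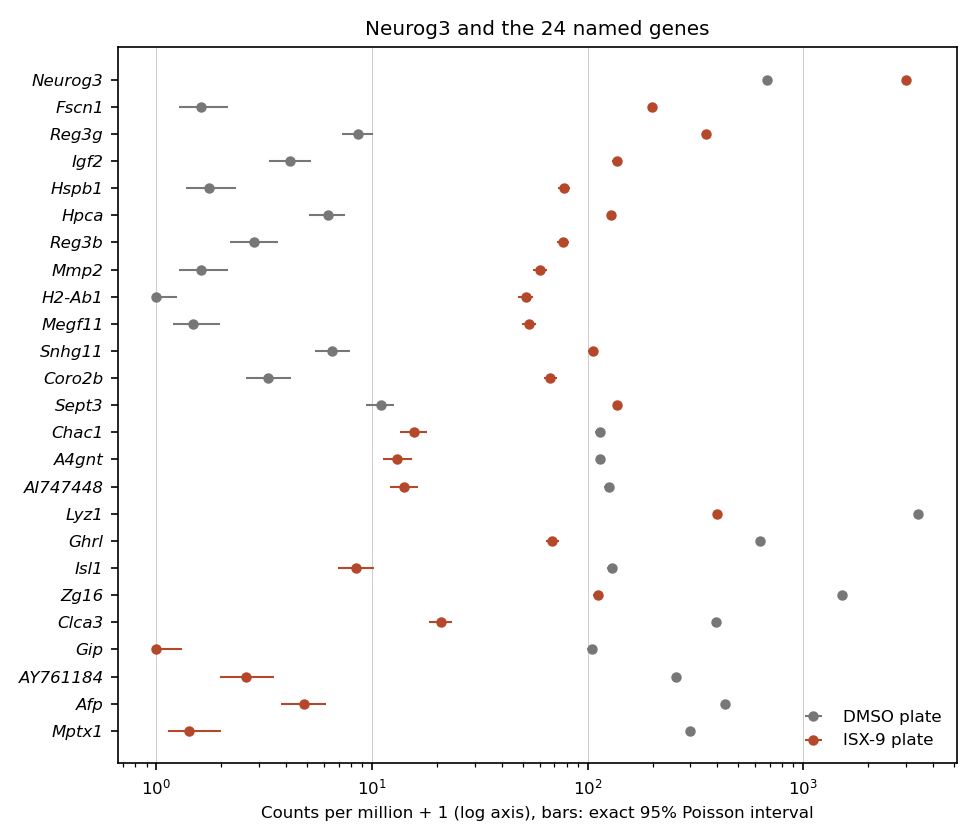
CPM + 1 on a log axis for Neurog3 and the 24 genes named by rank, 1 point per plate with its exact 95% Poisson interval. Neurog3 stood at 679 CPM in DMSO and 2990 CPM in ISX-9, and the 12 genes ranked highest were all below 10 CPM in the DMSO plate.

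The 12 genes with the highest log2 ratios were all below 10 CPM in the DMSO plate, and each had reads in at least 32 wells of the ISX-9 plate. Fscn1, which encodes the actin-bundling protein fascin, had the highest log2 ratio, 5.18, at 197.7 CPM (189.7 to 205.9) and in 45.2% of ISX-9 wells against 0.610 CPM (0.279 to 1.16) and 1.0% of DMSO wells. The antimicrobial lectin genes Reg3g (352.7 against 7.59 CPM) and Reg3b (76 against 1.83 CPM) had log2 ratios of 4.83 and 3.57. The growth factor gene Igf2 stood at 135.5 CPM in 38.97% of ISX-9 wells against 3.19 CPM in 1.67% of DMSO wells, and the small heat shock protein gene Hspb1 at 77 against 0.746 CPM. H2-Ab1, a class II histocompatibility gene, had 598 reads in 54 ISX-9 wells (50.7 CPM) and no read in DMSO. Its ISX-9 level was 249.2-fold above the DMSO floor of 3 counts, which covers counting error only. The others were Hpca (log2 ratio 3.70), Mmp2 (3.52), Megf11 (3.39), Snhg11 (3.38), Coro2b (3.28) and Sept3 (3.24), of which Hpca, a neuronal calcium sensor gene, was read in 42.4% of ISX-9 wells and 4.33% of DMSO wells. The highest single well held 4.59% of the ISX-9 reads of Fscn1 and 5.13% of those of Igf2, but 37.2% of those of Reg3b and 26.6% of those of Mmp2.

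Among the 12 genes with the lowest log2 ratios, Zg16, Lyz1, Afp, Gip, Ghrl and Isl1 are on the fixed goblet, Paneth, enterochromaffin or peptidergic marker lists and the others on none of the marker lists. The mucosal pentraxin gene Mptx1 stood at 296.6 CPM in DMSO (287.9 to 305.5) and 0.424 CPM in ISX-9 (0.138 to 0.989), a log2 ratio of -5.80. Afp, which encodes alpha-fetoprotein, stood at 434 against 3.81 CPM (-5.64), AY761184 at 255.04 against 1.61 CPM (-5.30), Clca3 at 392 against 19.8 CPM (-4.00) and the goblet cell lectin gene Zg16 at 1507 CPM in DMSO, with a log2 ratio of -3.70. The incretin hormone gene Gip had 1530 reads in DMSO (103.7 CPM) and none in ISX-9. Its DMSO level was 408-fold above the ISX-9 floor of 3 counts, a floor that covers counting error only. Isl1, an endocrine transcription factor gene, had a log2 ratio of -3.42, the ghrelin gene Ghrl -3.13 (but -0.16 as a mean over wells and -0.16 in thinned wells), the Paneth cell lysozyme gene Lyz1 -3.08, AI747448 -2.83, A4gnt -2.79 and Chac1, a stress-induced gene of glutathione breakdown, -2.58. Several of these levels came from few wells: the top 3 wells held 92.9% of the DMSO reads of Zg16, 86.7% of those of Gip, 84.3% of those of Afp and 74.8% of those of Mptx1, against 26.7% for Lyz1. With the highest well of each plate left out, log2 ratios were -5.65 for Zg16, -3.67 for Gip, -4.43 for Afp and -5.14 for Mptx1.

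Genes of the endocrine lineage went in both directions. Of 15 measured pan-endocrine transcription factors, 10 had positive and 5 negative log2 ratios, and the median of 0.75 was above all random lists (percentile 100). Insm1 stood at 404 against 150 CPM (log2 ratio 1.40) and Runx1t1 at 594 against 262.2 CPM (1.17), beside the higher Pax4 and the lower Isl1 given above. Of 10 measured enterochromaffin markers, which mark the serotonin-producing cells, 5 were positive and 5 negative. Their median of -0.23 lay at percentile 0.36, but it changed sign in thinned wells (0.10). Beside Afp, Reg4 stood at 421 against 1439 CPM (-1.76) and Chga, a granule protein gene, at 863 against 1639 CPM (-0.92), whereas the vesicular monoamine transporter gene Slc18a1 stood at 548 against 278.5 CPM (0.96). Tph1, the rate-limiting enzyme gene of serotonin synthesis in the gut, stood at 484 against 717 CPM (-0.56), while it was read in 46.6% of ISX-9 wells and 44% of DMSO wells. The 9 measured serotonin genes had a median of 0.10 (percentile 44).

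Of 12 measured peptidergic enteroendocrine markers, 10 had negative log2 ratios, 6 of them at least 2-fold, and the median of -1.08 lay below all random lists. Apart from Gip, Ghrl and Isl1, the peptide YY gene Pyy stood at 35.9 against 205.4 CPM (-2.36), but 1 well held 76.4% of its DMSO reads, and without the highest wells its log2 ratio was -0.92. The neurotensin gene Nts went the other way, at 278.3 against 20.5 CPM (3.47), but the top 3 wells held 86.4% of its ISX-9 reads and 99.7% of its DMSO reads. The 10 measured peptide hormones had a median of -0.58, with 4 positive and 6 negative, and this median became 0.10 in thinned wells. The 13 measured secretory granule genes had a median of 0.14 (percentile 57.2), with Cplx2 at 505 against 213.2 CPM (1.23) and Snap25 at 110 against 51.9 CPM (1.02).

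Most Paneth and goblet markers were lower in the ISX-9 plate. Of 6 measured Paneth markers, 5 were at least 2-fold lower and the median was -1.83, below all random lists. Itln1 stood at 1012 against 4756 CPM (-2.23), Ang4 at 1228 against 3339 CPM (-1.44) and Mptx2 at 1.53 against 30.9 CPM (-2.46). All 8 measured goblet markers were lower, 5 of them at least 2-fold, with a median of -1.24. The main intestinal mucin gene Muc2 stood at 501 against 1716 CPM (-1.77), Fcgbp at 439 against 1182 CPM (-1.42) and Spink4 at 621 against 1661 CPM (-1.41). Of 7 measured stem cell markers, 5 were lower and the median was -0.50 (percentile 0.035), with Ascl2 at 51.3 against 154.9 CPM (-1.50), Gkn3 at 1.44 against 20.7 CPM, Slc12a2 at 531 against 939 CPM (-0.82) and Lgr5 at 145.3 against 207.7 CPM (-0.50). The 12 cycling markers had a median of 0.06 (percentile 22.4), from -0.49 for Mcm5 to 0.77 for Cdc20. The 7 measured enterocyte markers had a median of 0.18 (percentile 61.8), but 0.68 in thinned wells, above the central 95% of random lists there, and lay on both sides of zero, among them Anpep at -0.27, Reg3g at 4.83 and Sis at 442 against 233.7 CPM (0.90). The 4 measured tuft markers were all positive (median 0.84, percentile 99.3), but the median in thinned wells, 0.60, lay within the random lists there, tuft-like wells numbered 4 in DMSO and 3 in ISX-9, and the highest single well held 64.7% of the ISX-9 reads of Dclk1. Of 8 immune and mesenchymal markers, 1 reached 10 CPM, and no median was taken.

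**Figure D2:**
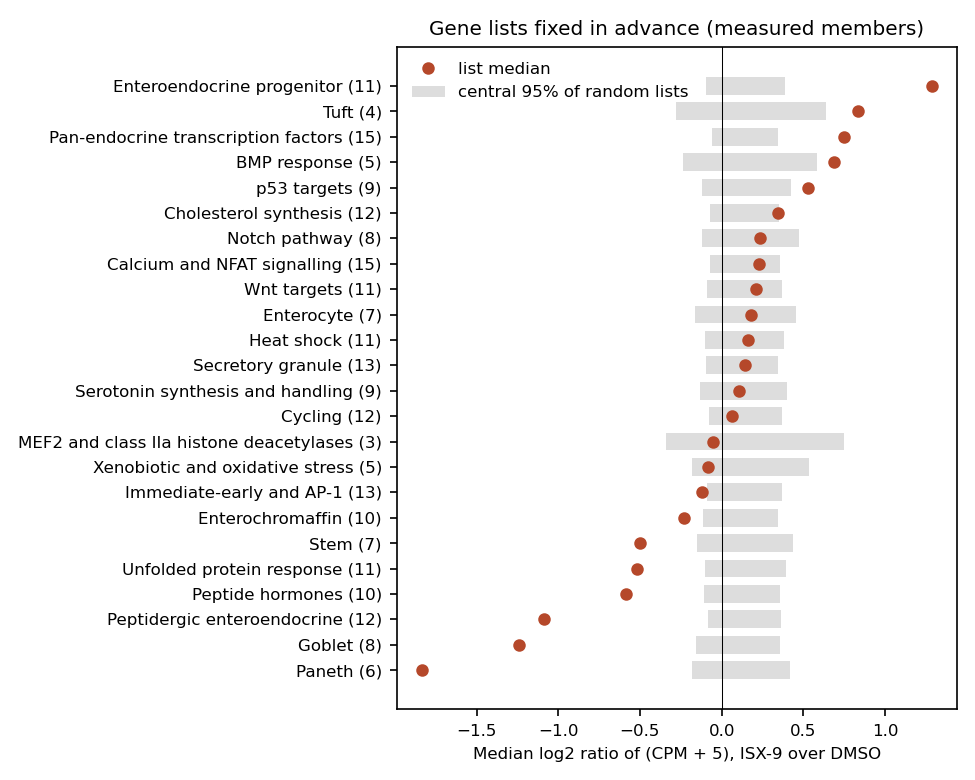
Median log2 ratio of (CPM + 5), ISX-9 over DMSO, of the measured members of each list (points, number of members in brackets), with the central 95% of random lists matched on expression (grey bars). The enteroendocrine progenitor list, at 1.28, and the Paneth list, at -1.83, were at the opposite ends.

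Among the pathway lists, the unfolded protein response had the lowest median after the peptide hormones, -0.52, with 10 of 11 measured members negative, below all random lists. Beside Chac1, Herpud1 stood at 40.7 against 100.04 CPM (-1.20), Trib3 at 5.08 against 17 CPM (-1.13) and Atf4 at 197.8 against 351.4 CPM (-0.81). Within classes the list median was -0.90 in enterochromaffin-like, -0.39 in cycling-like, -0.13 in goblet-like, 0.00 in progenitor-like and 0.19 in peptidergic-like wells, so the mix of classes, with fewer goblet-like wells in ISX-9, was not separated from the level of these genes. All 5 measured BMP response genes were positive (median 0.69, percentile 98.9, and 0.82 in thinned wells, within the random lists there), with Id1 at 71.9 against 36.5 CPM (0.89) and Id3 at 41.2 against 18.4 CPM (0.98). Of 9 measured p53 targets, 8 were positive (median 0.53, percentile 99.4, but 0.27 in thinned wells, within the random lists there), with Zmat3 at 37.3 against 16.5 CPM (0.97). The 12 cholesterol synthesis genes had a median of 0.34 (percentile 96.8, inside the central 95% of random lists, and 0.63 in thinned wells, above it there), and 11 were positive, with Dhcr7 at 88.7 against 51.3 CPM (0.74).

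Calcium signalling, which ISX-9 is known to engage, did not stand apart as a list. The 15 measured calcium and NFAT genes had a median of 0.23 (percentile 76.6), although Rcan1, a known NFAT target, stood at 22 against 6.10 CPM (1.28) and Camk2b at 93.3 against 46 CPM (0.95). The 13 immediate-early genes had a median of -0.12 (percentile 1.09), which lay within the random lists when CPM was averaged over wells (-0.04). Nr4a2 stood at 6.27 against 27 CPM (-1.50) and Nr4a1 at 31.1 against 16.1 CPM (0.78). The medians of the Notch (0.23, percentile 69.7), Wnt target (0.21, percentile 72.4), heat shock (0.16, percentile 62.5), xenobiotic and oxidative stress (-0.09, percentile 6.94) and MEF2 and histone deacetylase lists (-0.05, percentile 20.3, 3 genes measured) lay within the central 95% of random lists, although the Notch median was 0.74 in thinned wells, above it there. Within them the Wnt pathway factor gene Lef1 stood at 33.5 against 2.30 CPM (2.40) and Hspa1b at 126.3 against 59.2 CPM (1.03).

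Clustering of the 590 kept wells gave 11 clusters, 7 of which could be named. The enteroendocrine progenitor-like class (cluster 7), with Neurog3 among its top 10 genes, held 48 of 290 ISX-9 wells, 16.6% (Clopper-Pearson interval 12.5 to 21.3), and 7 of 300 DMSO wells, 2.33% (0.943 to 4.75). When all listed and named genes were kept out of the clustering, the shares were 21.03% and 3.0%. The goblet-like class (clusters 5 and 6) held 12.1% of ISX-9 wells (8.55 to 16.4) and 26.7% of DMSO wells (21.7 to 32.1), and 6.21% and 13.3% when clustered without those genes. Cluster 6 was led by the Paneth marker Lyz1, with Defa24 also in its top 10. No class was named Paneth, so the goblet-like class may hold Paneth cells too. Cluster 1, of low depth, had 4 Paneth markers above the limits (Lyz1, Ang4, Itln1 and Defa24). It would be named Paneth-like by the count of markers alone, and was left unnamed for Rn45s and Lars2. That cluster held 7.59% of ISX-9 and 21.7% of DMSO wells. The progenitor-like and goblet-like classes kept the direction of their difference under every alternative tried, while the sizes varied: with clusters named by the count of markers alone, clusters 2 and 8 joined the progenitor-like class, at 51.7% of ISX-9 and 11% of DMSO wells. The sort selects reporter-positive cells, so the shares describe the sorted fraction and not the organoid.

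The direction was not stable for the enterochromaffin-like, peptidergic and cycling-like classes, and the tuft-like class was not followed under alternatives. Enterochromaffin-like wells (cluster 3) made up 6.21% of ISX-9 and 14.7% of DMSO wells, but 36.9% and 23% at resolution 0.6. Peptidergic enteroendocrine-like wells (cluster 10) made up 2.76% and 8.33%, but 14.8% and 5.33% when clustered without the listed and named genes. In that run the class held 43 ISX-9 wells, 33 of them wells of cluster 8, described below. Cycling-like wells (cluster 9) made up 3.79% and 10%, but 17.9% and 14.3% at resolution 0.6, and 18.6% and 16.3% when clusters were named by the count of markers alone, which added cluster 4. Unnamed clusters held 57.6% of ISX-9 and 36.7% of DMSO wells. Of these, cluster 8, with Hpca, Dclk2, Pecam1, Sis, Runx1t1, Cdkn1c and Fev among its top 10 genes, held 49 ISX-9 wells and 1 DMSO well, and cluster 4, led by Reg3b, Reg3g and Clu, held 43 and 19. With 1 library per treatment, a cluster mostly of 1 library may be that library and not a cell type. Clusters 1 and 2 had low depth, with medians of 6329 and 6333 reads: cluster 1, with Lars2, Rn45s and defensin reads, held 22 ISX-9 and 65 DMSO wells, and cluster 2, led by Kcnb2 and Celsr3, held 53 and 25.

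**Figure D3:**
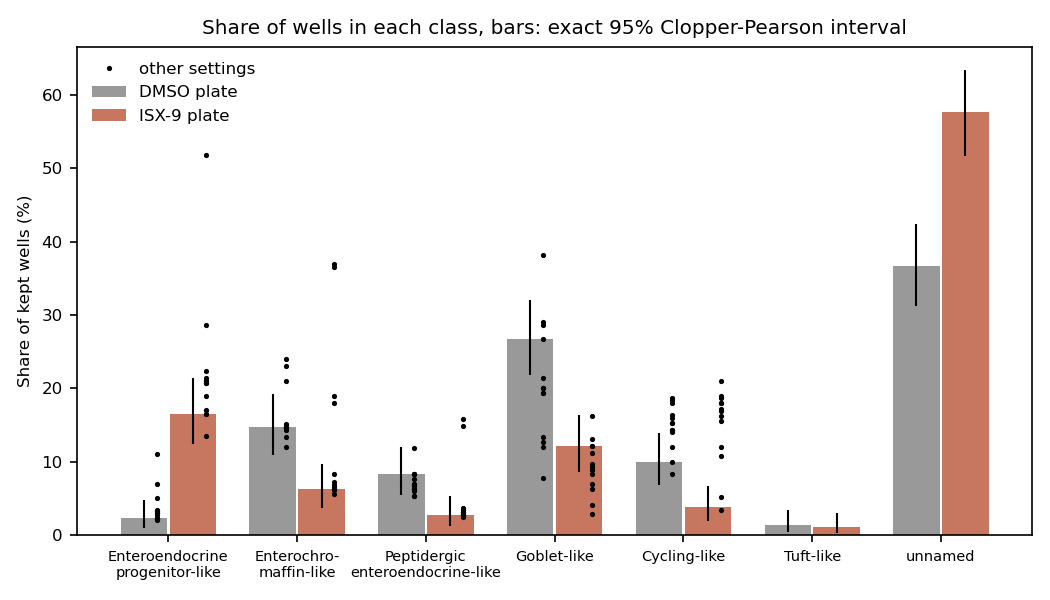
Share of kept wells in each class (bars, with exact 95% Clopper-Pearson intervals) in the DMSO and ISX-9 plates, and the shares under the other settings (black points, drawn for the first 5 classes). The progenitor-like share was 2.33% in DMSO and 16.6% in ISX-9, while the order of the plates turned under some settings for the enterochromaffin-like, peptidergic and cycling-like classes.

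Within progenitor-like wells, a class led by Neurog3 among other genes, Neurog3 stood at 13481 CPM in ISX-9 (13303 to 13660) and 9636 CPM in the 7 DMSO wells (9231 to 10055), a log2 ratio of 0.48 against 2.13 over all wells. It was lower in ISX-9 in enterochromaffin-like wells (-0.36), goblet-like wells (-0.40) and peptidergic-like wells (-1.94) and higher in cycling-like wells (2.70). In contrast, Fscn1, Igf2, Hspb1, H2-Ab1, Mmp2, Snhg11 and Coro2b had at least 2-fold higher (CPM + 5) in ISX-9 in all 5 classes compared. For Mmp2, Hspb1 and H2-Ab1 a 2-fold difference was not shown in progenitor-like wells. They had no read in the 7 DMSO wells and at most 18.3 CPM in ISX-9. A floor of 3 counts is high in so few wells, where the lowest level of a named gene with a read was 4.54 CPM (A4gnt). Fscn1 stood at 20.9 CPM in the 8 peptidergic-like ISX-9 wells, where the lowest such level was 10.5 CPM (Reg3g), so few reads carry it. The level of Mmp2 in these wells, 649.4 CPM, may come from a single well, as the highest well held 26.6% of its ISX-9 reads. In goblet-like wells Igf2 stood at 155.4 CPM, in 17 of 35 ISX-9 wells, against 1.83 CPM, in 3 of 80 DMSO wells, and Hspb1 was read in 19 of 35 ISX-9 wells and in none of the 80 DMSO wells. Hpca had 1.76 CPM in goblet-like ISX-9 wells and 203.5 CPM in progenitor-like ISX-9 wells, and Megf11 had 3.51 and 276.2 CPM, while progenitor-like DMSO wells had 9.09 CPM of Hpca and 22.7 CPM of Megf11.

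Goblet-like wells of both plates had similar levels of several goblet genes, with Muc2 at 3695 CPM in ISX-9 and 5250 CPM in DMSO (-0.51), Agr2 at 1450 and 1520 CPM (-0.07) and Tff3 at 9697 and 6741 CPM (0.52). Lyz1 was lower there, at 2328 against 8733 CPM (-1.91), as were Zg16, at 37.8 against 5027 CPM (-6.88), and Mptx1, with no read in ISX-9 against 934 CPM. These 3 genes also help define the goblet-like clusters. A different mix of goblet and Paneth cells within the class was not separated from a lower level of them. The highest single well held 90.9% of the ISX-9 reads of Zg16 and lay outside the goblet-like class. The log2 ratio of Zg16 within the class thus depends on where that well was clustered. In enterochromaffin-like wells Chga stood at 15042 CPM in ISX-9 and 15592 CPM in DMSO (-0.05), Tac1, the substance P precursor gene, at 6878 and 9152 CPM (-0.41) and Tph1 at 3877 and 5486 CPM (-0.50), whereas Reg4 stood at 2313 and 9865 CPM (-2.09) and Afp at 120 and 4817 CPM (-5.27). The 8 peptidergic-like ISX-9 wells had 40053 CPM of the cholecystokinin gene Cck, against 21819 CPM in the 25 DMSO wells (0.88). Nts stood there at 8198 against 209.4 CPM (5.26) and Isl1 at 115.2 against 1173 CPM (-3.29). Ghrl, at 1948 against 5672 CPM (-1.54), was instead higher in ISX-9 when averaged over wells (0.86).

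Cluster 8 combined progenitor and enterochromaffin genes. Its 49 ISX-9 wells had 4008 CPM of Neurog3, 1357 CPM of Tph1, 6745 CPM of Tac1 and 2727 CPM of Fev, a serotonergic transcription factor gene. In ISX-9 progenitor-like wells the same genes stood at 13481, 116.1, 20.8 and 344.1 CPM, and in ISX-9 enterochromaffin-like wells Neurog3 stood at 361.7 CPM and Fev at 1263 CPM. When clustered without the listed and named genes, 33 of the 49 ISX-9 wells of cluster 8 fell into a cluster named peptidergic enteroendocrine-like.

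Abundant transcripts were also read at low levels in wells of other classes. Cck had a read in 73.8% of DMSO goblet-like wells, at 50.5 CPM and a median depth of 46418 reads, against 88% of DMSO peptidergic-like wells, at 21819 CPM and a median depth of 37731 reads. In thinned wells these shares were 5% and 68%. Shares of wells with a read are therefore not shares of cells that express an abundant gene, and the shares in thinned wells and the CPM carry the comparison. For Lyz1 the shares in thinned wells were 17.2% in ISX-9 and 42.7% in DMSO, for Zg16 1.72% and 8.67%, for Fscn1 19% and 0%, and for Hpca 20.7% and 2.33%.

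**Figure D4:**
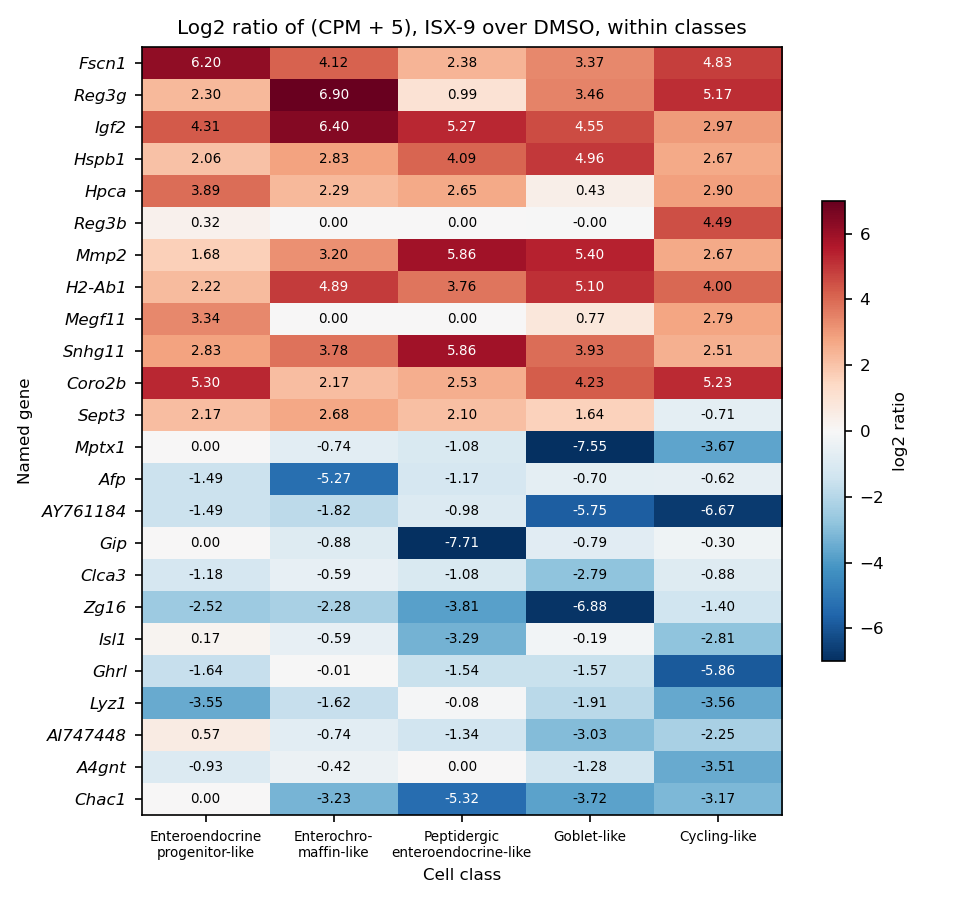
Log2 ratio of (CPM + 5), ISX-9 over DMSO, of the 24 named genes (rows) within 5 named classes (columns), with the value printed in each field. Igf2 lies at or above 2.97 in all 5 classes, while the value of Afp is -5.27 in enterochromaffin-like wells and lies between -1.49 and -0.62 elsewhere.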

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

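The tests on class mix, depth, sex, levels within goblet-like wells and the spread between wells were chosen only after the result was seen. ERCC spike-ins, used above only as an alternative scale, took 5.49% of all reads in the ISX-9 plate and 4.27% in the DMSO plate, a higher share than in the control. Kept wells had 16.2 nuclear reads per spike-in read in ISX-9 and 19.3 in DMSO.

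The first pattern is the set of 12 genes below 10 CPM in DMSO and read in many ISX-9 wells. A different mix of cell classes would leave equal levels within a class, and the median log2 ratio of the 12 genes within goblet-like wells was 3.69. The genes were named for the highest ratios over all wells, so a high median within a class was largely set by that choice. It therefore does not decide whether a different mix accounts for them. Hpca (0.43) and Megf11 (0.77) stayed low there and Reg3b had 6.15 against 6.17 CPM. Hpca was at least 2-fold higher in the 4 other classes compared. Megf11 was so in 2 classes, with 3.34 in progenitor-like wells, of which DMSO had 7, and Reg3b in 1. The mix of classes thus remains open for the set, Megf11 and Reg3b included. Depth does not account for the set, since 12 of the 12 genes stayed at least 2-fold higher after every well was thinned to 2000 reads, and the DMSO plate had more reads. Another animal, organoid line or library batch cannot be told apart from the treatment, because each treatment has 1 plate: Y-linked genes had a log2 ratio of 0.18, which shows only that both plates hold male cells, and an effect of ISX-9 is untested and open too.

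The second pattern is the lower level of goblet and Paneth genes. Whether fewer goblet-like wells account for the listed genes remains open, since within goblet-like wells the median log2 ratio of the 14 goblet and Paneth list genes was -0.43 (95% interval over resampled wells -0.95 to 0.06), with 11 of them lower and 5 at least 2-fold lower, and was -0.34 for the goblet and -0.69 for the Paneth list, against -1.24 and -1.83 over all wells. The 5 named genes with their highest DMSO level in goblet-like wells were Mptx1, Clca3, Zg16, Lyz1 and A4gnt. Their median within these wells was -2.79 (-7.20 to -1.57). They were named for the lowest ratios over all wells, so a low median within the class was largely set by that choice. It therefore does not decide whether fewer such wells account for them. In addition, 3 wells held most DMSO reads of Zg16 (92.9%), Mptx1 (74.8%) and Clca3 (73.4%) and 97% of the ISX-9 reads of Clca3. A single well outside the class held 90.9% of the ISX-9 reads of Zg16. The chance absence of a few such cells thus stays open. Background RNA in other wells, as the whole cause, would put most of the DMSO reads of the 14 genes outside the class, but 25.3% lay there, while in ISX-9, with fewer goblet-like wells, 48.6% lay inside the class, so a part from background stays open. A treatment effect on these genes and a difference between the plates as such were not separated.

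The third pattern is cluster 8, with 49 ISX-9 wells and 1 DMSO well. A shift of the whole ISX-9 plate may contribute: ISX-9 wells of the goblet-like class had 1.75 times and those of the enterochromaffin-like class 1.85 times as many neighbours from their own plate as the class's plate shares give, with 1.31 in the cycling-like and 1.47 in the peptidergic-like class, and 1.93 for the 7 DMSO wells of the progenitor-like class, whose ISX-9 wells hold too much of the class to show a high ratio. With each gene centred within its plate, 38 of the 50 wells of cluster 8 fell into 1 cluster that held 47 ISX-9 and 14 DMSO wells. Doublets of progenitor-like and enterochromaffin-like cells would hold levels between those classes, and 9 of the 15 measured pan-endocrine transcription factors lay above both, 5 of them more than 1.5-fold, which met the number set beforehand. After the values were seen this verdict was withdrawn and left open, because 1 of the 5, Isl1, was read in 1 ISX-9 well of the cluster, and those above both by more than the 95% interval over resampled wells numbered 3 (Fev, Runx1t1 and Etv1), and 2 (Pax6 and Etv1) in the matching cluster found without the listed and named genes, so doublets, the plate and the untested effect of ISX-9 all remain open.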

How the results depend on the processing

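No paired analysis was possible because there is 1 plate per treatment. All alternative values of the 24 named genes kept their direction, and all but 2 stayed at least 2-fold, the exceptions being Ghrl as a mean over wells (-0.16) and in thinned wells (-0.16), against -3.13. For shares of wells this direction was set in advance, because genes were named only if that share differed the same way. Every alternative reprocessed the same plates, so agreement among them is no replicate check. Among the 50 named and listed genes with a main difference of 2-fold or more, 600 of 600 alternative values kept their direction. The progenitor, peptidergic, Paneth, goblet, stem, pan-endocrine and unfolded protein response list medians stayed outside the central 95% of random lists under every alternative run. Unless stated, the cause was not tested for any value below, except that an alternative with fewer reads or wells rests on fewer counts. Leaving out Rn45s, wells of clusters 1 and 2, each gene's highest well, or the named and listed genes, and naming clusters without the conditions on the top 10 genes, were chosen after seeing the data.

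For Neurog3, log2 ratio values were 2.13 in the report, 1.93 with median-of-ratios factors, 1.88 with ERCC scaling, 1.67 as a mean over wells, 1.69 in thinned wells, 2.24 without the top 5% of wells, 0.56 as a share of wells, 2.03 without Rn45s, 2.28 without clusters 1 and 2 and 2.18 without its highest wells.

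The enterochromaffin list median, -0.23, became 0.10 in thinned wells, 0.19 without the top 5% of wells and 0.075 as a share of wells, and -0.10 without each gene's highest well. The peptide hormone median, -0.58, became 0.10 in thinned wells. The cycling median, 0.06, became -0.086 without the top 5% of wells and -0.13 as a share of wells. The Immediate-early and AP-1 list, median log2 ratio -0.12, was -0.036 as a mean over wells and -0.049 in thinned wells. In thinned wells the p53 targets median, 0.53, became 0.27, the BMP response median, 0.69, became 0.82 and the Tuft median, 0.84, became 0.60, each within the random lists there, while the Notch pathway median, 0.23, became 0.74, the Cholesterol synthesis median, 0.34, became 0.63 and the Enterocyte median, 0.18, became 0.68, each above the central 95% of random lists there.

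Differences in class shares are in percentage points, ISX-9 minus DMSO. The Enteroendocrine progenitor-like share of wells, ISX-9 minus DMSO, 14.2, was 21.6 with genes centred within plates, 16.4 in thinned wells, 18.99 without clusters 1 and 2 and 40.7 with clusters named without the conditions on the top 10 genes. The Enterochromaffin-like share of wells, ISX-9 minus DMSO, -8.46, turned to 13.9 at resolution 0.6, 5.63 with 30 principal components, 12.6 in thinned wells and 2.93 without the named genes, and was -12.6 without clusters 1 and 2. The Peptidergic enteroendocrine-like share of wells, ISX-9 minus DMSO, -5.57, turned to 10.5 under the looser filter and 9.49 without the named and listed genes. In the latter run the class took in 33 of the ISX-9 wells of cluster 8. The Goblet-like share of wells, ISX-9 minus DMSO, -14.6, was -9.68 at resolution 1.5, -10.02 without cycling markers, -13.1 with centring, -7.86 in thinned wells, -10.2 and -11.2 under the stricter and looser filters, -4.82 without the top 5% of wells, -21.8 without clusters 1 and 2, -4.39 without the named genes and -7.13 without the named and listed genes. The Cycling-like share of wells, ISX-9 minus DMSO, -6.21, turned to 3.60 at resolution 0.6, 2.21 at resolution 1.5, 1.56 with 30 principal components, 2.60 in thinned wells, 2.65 and 2.42 under the stricter and looser filters, 0.0267 without the top 5% of wells, 0.30 without the named and listed genes and 2.29 with clusters named without the conditions on the top 10 genes, and was -0.48 with centring, -9.17 without clusters 1 and 2 and -0.76 without the named genes. Part of the kept wells did not reach the stricter filter of 6000 reads and 1000 genes, under which the progenitor-like shares were 18.9% in ISX-9 and 3.42% in DMSO.

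For Afp within Enterochromaffin-like wells, log2 ratio -5.27, the values were -3.30 as a mean over wells, -7.10 at resolution 0.6, -3.21 in thinned wells and -3.83 without the top 5% of wells. For Zg16 within Goblet-like wells, log2 ratio -6.88, they were -5.78 as a mean over wells and -5.80 in thinned wells. For Nts within Peptidergic enteroendocrine-like wells, log2 ratio 5.26, they were 4.90 as a mean over wells, 4.67 in thinned wells and 4.63 without the top 5% of wells, while Ghrl, at -1.54, turned to 0.86 as a mean over wells and 0.98 in thinned wells.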

Other observations

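Genes in this part were chosen after their values were seen, and the test on the whole excess of nearly unread genes was chosen only after the result was seen. Some genes that had almost no reads in the DMSO plate were read in the ISX-9 plate, and those named here are examples that do not stand for a group. The maternally expressed noncoding gene H19 (chromosome 7) stood at 26.5 CPM in 13 ISX-9 wells and had 1 read in DMSO. The pluripotency factor gene Sall4 stood at 16.9 CPM in 25 wells against 5 reads, Sox11 at 20.5 CPM in 28 wells against 3 reads, the intermediate filament gene Nes at 15.7 CPM in 23 wells, Igfbpl1 at 28.2 CPM in 59 wells and Twist1 at 14.2 CPM in 13 wells, the last 3 with no read in DMSO. The 3513 genes with at most 5 reads in the DMSO plate added up to 2793 CPM in ISX-9, and to 2742 CPM without H2-Ab1, the highest of them. The 3083 genes with at most 5 reads in ISX-9 added up to 1326 CPM in DMSO, and to 1029 CPM without Mptx1. The sort selects reporter-positive cells from organoids, which speaks against mesenchymal cells; a few may still contribute, as 1 ISX-9 well reached 1473 CPM for Col1a1, Col1a2 and Col3a1 together, above the 1000 CPM set beforehand, but leaving out the 7 ISX-9 wells with a collagen read removed 6.45% of the excess.

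Because Igf2 was among the genes with the highest ratios and Cdkn1c among those that lead cluster 8, other imprinted genes were examined as a hypothesis. Of 9 measured members 8 were positive, with Grb10 at 44.1 against 2.64 CPM and Phlda2 at 35.4 against 11.3 CPM, and the median of 0.43 lay at percentile 95.97, inside the central 95% of random lists, so the bound set beforehand was not reached. This outcome depends on the imprinted genes Meg3 (45.8 against 0.813 CPM) and Kcnq1ot1, left out because they had been noticed before: with Meg3 the median was 0.56 (percentile 99.55) and with both 0.43 (percentile 97.8), past the bound, so the question stays open. Dlk1 (17.1 against 1.49 CPM) and Peg10 (11.6 CPM against no read) were too low to be counted as measured.

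A second hypothesis, that H2-Ab1 belongs to a wider interferon and antigen presentation response, stays open: the 9 measured members lay at percentile 53.84 (median 0.14), between the bounds set beforehand. The class I genes H2-K1 (1630 against 947 CPM) and B2m (2068 against 1465 CPM) were higher in ISX-9, and the interferon targets Ifit1 (93.7 against 242.4 CPM) and Isg15 (27.2 against 54.4 CPM) were lower. H2-Aa, the partner of H2-Ab1, stood at 0.847 against 0.610 CPM.

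Another hypothesis was that the lower Gip and higher Nts reflect a different mix of jejunal and ileal cells. The median log2 ratio of distal genes exceeded that of proximal genes by 1.24, which met the bound of 1 set beforehand, but with genes counted from a mean of 1 CPM and not from 10 CPM as for the other lists. The question was left open after the values were seen, because the difference rested on Hoxb6, Hoxb7 and Hoxb8, each at most 10.3 CPM, and from 10 CPM Osr2 (-0.06) was the single distal gene, beside the proximal Gata4 (0.01) and Onecut2 (0.03), too few to decide. The other 29 Hox genes added up to 309.9 CPM in ISX-9 and 161.2 CPM in DMSO, a log2 ratio of 0.92, short of the bound of 1 set beforehand, which leaves open whether they are higher as a group.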
